A study of Drosophila melanogaster with 8 samples.

How the data were processed

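RNA from neuroblasts and ganglion mother cells of the ventral nerve cord of Drosophila melanogaster embryos was compared on 8 two-colour arrays. Per the labels, the embryos were at stage 11, developed at 25 °C, and each sample came from 50 to 100 cells. The labels' protocols state that the RNA was reverse transcribed, that the cDNA was tailed with terminal transferase and amplified by PCR, and that Cy3 or Cy5 was incorporated by Klenow extension from random primers. Mutant cells were homozygous for the ase1 allele of asense. The samples called wild type carried ase1 over the FM7 balancer chromosome with a KrGFP marker, so each control was heterozygous. The arrays form 5 mutant and wild-type pairs numbered 1, 3, 4, 5 and 6. Pairs 1, 4 and 5 have arrays a and b with the same source names in both channels, and these were averaged to 1 replicate. The series design speaks of 8 samples of each genotype, while the source names give 5, and pairs were used as replicates. SDs and p-values had n = 5 for the 7614 of 8295 tested features measured in all 5 pairs, and n = 4 for the others. Some alternative fits used other numbers of pairs or arrays. The mutant was labelled with Cy5 on 3 arrays (pairs 1 and 3) and with Cy3 on 5 arrays (pairs 4, 5 and 6). The labels do not say that the pairs came from separate embryos, so p-values measure the spread between these pairs, which can be partly technical.

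The deposited values are log ratios of the 2 channels for 14569 probes, read here as log2. The log base, the normalization, the scaling and the centring by the authors are not given in the sources used here. Base 10 was set aside because the largest size, 7.43, exceeds the 4.82 that a 16-bit scan allows on that scale. A natural log stays possible, and folds would then be larger. The median of each of the 8 columns was 0. Between 36.3% and 43.7% of the values on an array were exactly 0, and 3490 probes were 0 on all 8 arrays against 7.8 if the arrays were independent. These values were taken as not measured. The medians of the measured values lay between -0.18 and -0.02. The arrays gave 8200 to 9276 measured probes each, and the number of arrays limits the precision. Spot intensities were not used here.

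The direction of the ratios follows a rule set in advance. Asense is targeted in the mutant, and its log ratio was far below 0 on all 8 arrays in both dye orientations. The table therefore likely runs as mutant over wild type on every array, and signs are given on that basis.

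Probes were named through a platform annotation, with symbols updated through a gene table of the Release 6 plus ISO1 MT assembly, which was used only for names, neighbours and chromosome arms. Of the probes, 12657 had 1 gene symbol, 96 had several and 1816 had none. A match by gene identifier was found for 12011 and by accession for 107, and 98 symbols were updated. Values were averaged over the probes of a gene, and probes without a single name stayed separate. Among 234 genes with 2 or more tested probes, 78 had probes of opposite sign and 7 had called probes of opposite sign. Probe sequences were not used here, so cross-hybridisation between closely related genes such as the Hsp70 copies or the Dorsocross genes was not examined.

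A gene or unnamed probe was tested when it had a value in at least 4 of the 5 pairs. The mean log ratio was tested against 0, two-sided, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, and called at a Benjamini-Hochberg adjusted p below 0.05. All adjusted p-values of single genes come from limma. Gene lists were tested on genes measured in all 5 pairs with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were also run. Benjamini-Hochberg adjustment ran over the 21 of 24 lists with at least 3 such genes. Fry tests whether the genes of a list move, on balance, in 1 direction, and does not compare them with other genes. It was run on uncentred values only.

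The design, the 24 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names asense, the 12 largest increases and 12 largest decreases among named genes past the test with the same sign in all 5 pairs, every list member past the test, and up to 4 members with the smallest p where none passed. Other members are named beside their list as values, chosen after their values were seen. The alternatives changed the reading of direction, the dye term, the handling of repeat arrays, centring, scaling, array weights, probe averaging, missing values, moderation, the variance filter, the threshold and the replicates included. Keeping exact zeros, counting 8 arrays as 8 replicates, using array b alone and the gene lists without pair 3 were added after the data were seen. The procedure was tested on simulated data for the mutant against wild type comparison with 8295 features. It recovered 71 of 100 shifts of size 1 and 97 of 100 shifts of size 2, and called 8 of 8095 unshifted features. These counts hold for the simulated data, where 200 features were shifted, and do not give the rate of false calls on the real arrays. False calls from an offset shared within an array or from correlated genes were not measured. The median of all tested features was -0.07 in the real data, and centring the arrays kept 1285 of the 1517 calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.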

Results

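Expression was compared directly between asense mutant and control cells from the embryonic ventral nerve cord, on 8 arrays that form 5 pairs. The cells were neuroblasts, the neural stem cells, and ganglion mother cells, their daughters that divide once more into neurons or glia. Asense is a basic helix-loop-helix transcription factor of the achaete-scute complex expressed in neuroblasts, and the comparison asks which transcripts depend on it. Log ratios are mutant over wild type, a direction that is likely because asense itself was far below 0 on every array. They are read as log2.

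Asense (ase, on the X chromosome) had the largest log ratio by size of all features tested, -6.06 ± 0.47 (SD, n = 5 pairs, limma adjusted p = 4.231e-06). Its values ran from -6.51 to -4.81 on the 3 arrays with the mutant in Cy5 and from -6.49 to -5.74 on the 5 arrays with the mutant in Cy3. Of its 9 measured neighbours, among them the related genes achaete, scute and lethal of scute, 0 passed the test in limma. The log ratio was 0.72 for ac, -0.21 for sc and 0.08 for l(1)sc.

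In mutant cells, 3 of 9 measured prodifferentiation factors of ganglion mother cells fell (pros, nerfin-1 and lola), 6 of 20 S phase genes rose, and 5 of 17 Notch pathway and Enhancer of split genes rose while 2 fell. These 3 lists passed camera at the preset correlation, and each had an adjusted p = 0.865 with an estimated correlation. The adjustment gave that same value to most lists, so it does not rank them. Unadjusted, camera with an estimated correlation gave p = 0.1445 for prodifferentiation factors, 0.1774 for S phase and 0.1032 for the Notch list. Limma called 1517 of 8295 features at the adjusted threshold, 578 higher and 939 lower. Of these, 407 had a log ratio of at least 1 in size, 150 higher and 257 lower. The same sign in all measured pairs was found for 1462 of the 1517, which passing the test favours. Over all 8295 features tested it was found for 2858 (34.45%). Lower calls made up 61.9% of the total, but with each array centred on its measured values the split was 805 higher and 707 lower. The count fell to 936 without pair 1, 1040 without pair 3, 747 without pair 4, 597 without pair 5 and 1309 without pair 6. The higher calls alone fell to 349, 373, 275, 240 and 455 in the same order.

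The largest decreases after asense were in Tektin-C, a protein of ciliary and sperm-tail microtubules, at -4.39 ± 0.91 (SD, n = 5, limma adjusted p = 4.589e-04), CG3430 at -4.27 ± 0.57 and CG13711 at -3.89 ± 1.34. The glial determinant glial cells missing (gcm) came next at -3.77 ± 2.22 (adjusted p = 0.0131), with pairs between -6.31 and -1.07. CG14072 (-3.57), CG14111 (-3.23), the T-box gene Doc1 (-3.19) and the tetraspanin gene TM4SF (-2.94) also fell. So did CG8066 (-2.94), the ubiquitin hydrolase gene Uch (-2.86), the odd-skipped relative sob (-2.85) and CG18428 (-2.69). The largest increase was in MFS16, a predicted membrane transporter, at 4.69 ± 0.27 (SD, n = 5, limma adjusted p = 4.231e-06), followed by CG15098 at 4.19 ± 1.01. The cytochrome P450 gene Cyp4d1 (2.79), CG13738 (2.76), CG14736 (2.65), jtb (2.61), CG16813 (2.55) and the dynein assembly factor gene Dnaaf3 (2.26) rose. CG4570 (2.25), the aldehyde dehydrogenase gene Aldh-III (2.24), CG15345 (2.23) and hibris (hbs, 2.15), an immunoglobulin-domain adhesion protein, rose as well.

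**Figure D1:**
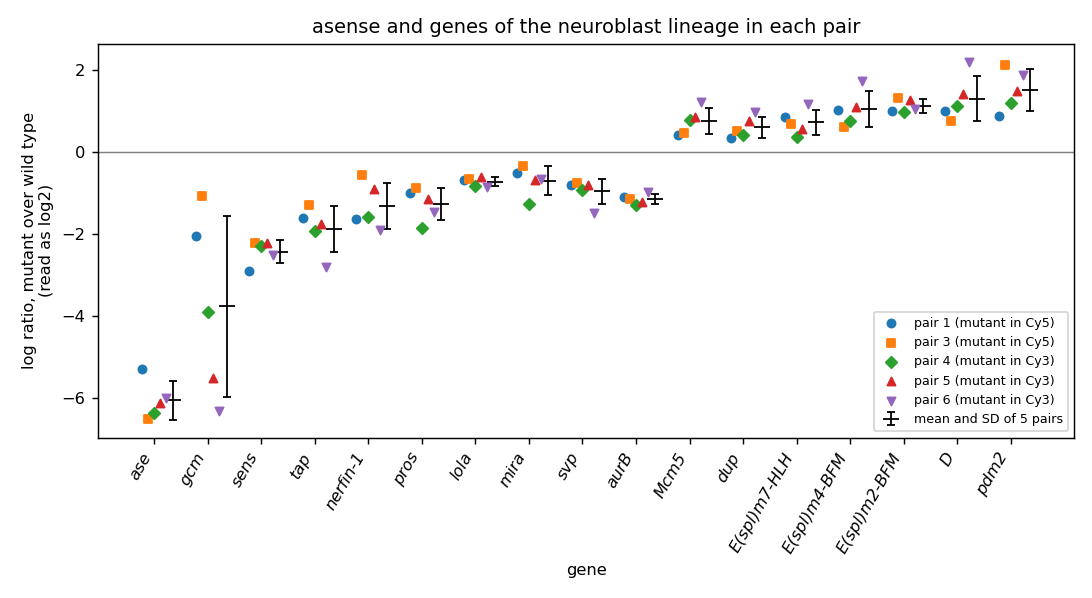
Log ratio of mutant over wild type, read as log2, for asense and 16 other genes past the test, with a symbol for each of the 5 pairs and bars for the mean and SD. Asense lies between -6.51 and -5.29 in the pairs, and gcm has the widest spread of the genes drawn, from -6.31 to -1.07.

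Of 9 measured ganglion mother cell and prodifferentiation factors 3 fell and 0 rose, 6 did not pass, and adjusted over the list alone 5 fell. The list median was -0.72, with a camera adjusted p = 0.0203 at the preset correlation and an adjusted p = 0.865 with an estimated correlation. Prospero (pros), the homeodomain factor that ends self-renewal in ganglion mother cells, fell by 1.27 ± 0.39 (SD, n = 5, limma adjusted p = 4.007e-03). The zinc finger gene nerfin-1, which keeps neurons differentiated, fell by 1.31 ± 0.56, and the BTB factor lola fell by 0.72 ± 0.11. The probes of lola did not all run the same way, with 3 of 12 tested probes not past the test, at 0.48, -0.14 and -0.47. Members not past the test were Hey (-1.23), eve (-0.96), jumu (-0.40), zfh1 (-0.40), brat (-0.36) and ftz (0.00). The camera adjusted p was 0.0940 without pair 6, 0.169 on genes measured on all 8 arrays (median -0.40), 0.176 with 8 separate replicates and 0.285 with array b alone. The lists of glia, mesoderm and hemocytes also had medians below 0 (-0.72, -0.57 and -0.42), as did trachea and gut (-0.68) and germ line (-0.16). Those of ectoderm (0.10) and midline (0.26) were above 0. In pair 3 the glia and mesoderm medians were above 0 (0.46 and 0.67) and the prodifferentiation median was -0.21, the nearest to 0 of the 5 pairs.

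Among proneural genes and their partners 2 fell and 0 rose. Senseless (sens), a zinc finger factor of sensory precursors, fell by 2.42 ± 0.29 (SD, n = 5, limma adjusted p = 1.705e-04), and tap, a neurogenin-type factor, fell too (-1.88 ± 0.57). The other 5 of 7 measured members did not pass, and adjusted over the list alone 2 rose and 2 fell. The list did not stand apart from other genes in camera (adjusted p = 0.718) but was called down in fry (adjusted p = 0.0147). Its members did not move together, and the list median was above 0 in pair 4 (0.40) and pair 6 (0.29). Of 7 measured neuronal genes 1 rose and 2 fell. The RNA-binding protein gene elav (-0.67) and the amyloid precursor homologue Appl (-0.43) fell and the POU gene acj6 (0.63) rose, with 1 higher and 2 lower adjusted over the list alone. Calls of elav and Appl were lost without any 1 of the 5 pairs and after centring (adjusted p = 0.0674 and 0.0861), and of the fits that left out 1 pair, the one without pair 1 kept that of acj6. Their camera adjusted p was 0.748 and their fry adjusted p 0.0336.

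Of 20 measured S phase genes 6 rose and 0 fell, 14 did not pass, and adjusted over the list alone 7 rose. The list median was 0.23, with a camera adjusted p = 0.0203 and an adjusted p = 0.865 with an estimated correlation. The helicase subunit genes Mcm5 (0.76 ± 0.32, SD, n = 5, limma adjusted p = 0.0148), Mcm2 (0.50) and Mcm6 (0.49) rose, as did the licensing factors dup (0.61) and Cdc6 (0.71) and the ribonucleotide reductase subunit RnrL (0.53). CycE (-0.09), PCNA (-0.16), Orc2 (-0.12) and PolA1 (0.72) did not pass. The median was 0.08 with array a of each pair only (camera adjusted p = 0.412) and 0.47 with array b of pairs 1, 4 and 5 (7.686e-04), and the adjusted p was 0.0908 on genes measured on all 8 arrays and 0.0836 with 8 separate replicates. The calls were sensitive to single pairs: 2 members were called without pair 1, 4 without pair 3, 1 without pair 4, 0 without pair 5 and 2 without pair 6, and camera gave an adjusted p = 0.0856 without pair 5. Fry did not call the list (adjusted p = 0.0848). With a dye term RnrL, Mcm2, Mcm6 and Cdc6 lost the call (limma adjusted p between 0.0643 and 0.0756). With array a only, each of the 6 lost it (limma adjusted p between 0.221 and 0.315). Of 19 mitosis genes measured, 1 fell and 0 rose, with the same count adjusted over the list alone. It was the Aurora B kinase gene aurB, at -1.14 ± 0.12 (camera adjusted p = 0.769 for the list, whose median was 0.03 and mean -0.03).

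Of 17 measured Notch pathway and Enhancer of split genes 5 rose and 2 fell, 10 did not pass, and adjusted over the list alone 11 rose and 3 fell. The fixed list held 24 genes. The receptor N, the ligands Dl and Ser, and the transcription factor Su(H) were not among the 17 measured. The list median was 0.56, with a camera adjusted p = 0.0203 and an adjusted p = 0.865 with an estimated correlation. The Bearded-family genes E(spl)m2-BFM (1.13 ± 0.16, SD, n = 5, limma adjusted p = 1.651e-03), E(spl)m4-BFM (1.06) and E(spl)malpha-BFM (1.05) rose, as did the repressor gene E(spl)m7-HLH (0.73) and sanpodo (spdo, 0.85), which promotes Notch signalling in asymmetric divisions. The coactivator mastermind (mam, -0.62) and the ubiquitin ligase neuralized (neur, -0.55) fell. Of the 2 mam probes 1 did not pass on its own (-0.37, limma adjusted p = 0.0558 among probes). Camera kept the list call in each fit that left out 1 pair, with 3 to 7 members higher and 0 or 1 lower. Its adjusted p was 0.0929 with array a only, 0.151 with each probe on its own, 0.0908 on genes measured on all 8 arrays and 0.0836 with 8 separate replicates.

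Neuroblast and temporal factors went in both directions. Of 12 neuroblast factors 1 rose and 3 fell, and adjusted over the list alone 1 rose and 4 fell. The adaptor gene miranda (mira, -0.69), klumpfuss (klu, -1.21) and seven-up (svp, -0.96) fell, and Dichaete (D, 1.31) rose. Of the 2 svp probes 1 did not pass on its own (-0.55, limma adjusted p = 0.0896 among probes). The neuroblast markers dpn (-0.44), wor (-0.11) and insc (-0.03) did not pass. Of 8 temporal series factors 2 rose (pdm2, 1.52, and D) and 1 fell (svp), and adjusted over the list alone 2 rose and 2 fell. The camera adjusted p was 0.748 for each list, and the temporal list had a median of -0.09 and a mean of 0.12. Among 17 asymmetric division genes the polarity kinase gene aPKC (0.74) rose and pros and mira fell, with 1 higher and 4 lower adjusted over the list alone and a camera adjusted p = 0.211.

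Of 8 measured glial genes 3 fell and 0 rose, namely gcm, repo (-1.20, n = 4) and the glutamine synthetase gene Gs2 (-1.61), and adjusted over the list alone 3 fell and 1 rose. The glial list had a camera adjusted p = 0.748. Its lower calls numbered 2, 4, 2, 2 and 1 without pairs 1, 3, 4, 5 and 6, with 1 higher without pair 6. With a dye term repo and Gs2 lost the call (limma adjusted p = 0.0687 and 0.05175). Of 6 mesoderm and muscle genes 2 fell, the fusion regulator lmd (-2.08) and slou (-0.75), with the same count adjusted over the list alone. Their camera adjusted p was 0.261, and 0.0182 with 4 members lower without pair 3, a fit chosen after the data were seen. With an estimated correlation the adjusted p was 0.865 over all pairs and 0.853 without pair 3. Of 8 hemocyte genes crq (-1.05) and Hml (-0.39) fell and Tig (0.90, n = 4) rose, with the same counts adjusted over the list alone, a camera adjusted p = 0.211 and a fry adjusted p = 0.0336. Of 10 ectoderm genes crb (0.52) and pyd (0.72) rose and 0 fell, again the same adjusted over the list alone, with a camera adjusted p = 0.7003. Limma called 0 of 3 midline genes, where Tl (0.72), vvl (-0.55) and sli (0.26) had adjusted p between 0.0531 and 0.322, and 1 was higher and 1 lower adjusted over the list alone. It called 0 of 3 tracheal and gut genes, with 0 calls adjusted over the list alone and a camera adjusted p = 0.791. There peb (-1.25), btl (0.70) and fkh (-0.68, with -2.86 in pair 6) had adjusted p of 0.0862, 0.128 and 0.295 in limma. Of 4 germ line genes bam (-0.69) fell, also adjusted over the list alone, with a camera adjusted p = 0.748.

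The remaining lists held scattered calls. Of 16 axon guidance genes Dscam1 (0.73) and unc-5 (0.62) rose and PlexB (-1.01) fell, and adjusted over the list alone 3 rose and 1 fell, with a median of -0.08 where camera pointed up. Of 12 patterning genes hedgehog (hh, 0.50) rose and odd (-1.16) fell. Of 8 apoptosis genes the caspase gene Dcp-1 (1.02) rose while egr (-0.67), grim (-0.66) and the inhibitor Diap2 (-0.46) fell. The lower apoptosis calls numbered 1, 1, 0, 0 and 1 without pairs 1, 3, 4, 5 and 6, with 1 higher each time. Of 37 ribosomal protein genes RpL27 (1.63) rose and RpS10a (-1.55), RpL37-2 (-1.45) and RpL17 (-0.64) fell, with a median of 0.09 where fry pointed down. For patterning, apoptosis and ribosomal genes the counts adjusted over the list alone were the same. Among Hox genes the 3 probes of Antp differed, with 1 lower on its own (-0.51, limma adjusted p = 0.0320 among probes) and others at -0.20 and 0.18. Neither Antp averaged over its probes (-0.20) nor Scr (-0.65, from -3.05 in pair 6 to 0.90 in pair 3) passed. Nor did the 6 heat shock genes pass, among them Hsp26 (-0.90, called at -0.99 with all 8 arrays and the pair as a random block), Hsp27 (0.16), Hsp70Ba (-0.31) and Hsp70Ab (-0.13). The dosage compensation gene msl-2 (0.94), the 1 measured gene of its list, rose but lost the call without pair 4 or pair 5. The sex of the embryos was not analysed here. Of 8 genes listed near asense elav and Appl fell. Camera gave an adjusted p of at least 0.748 for each of these lists that it tested.

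**Figure D2:**
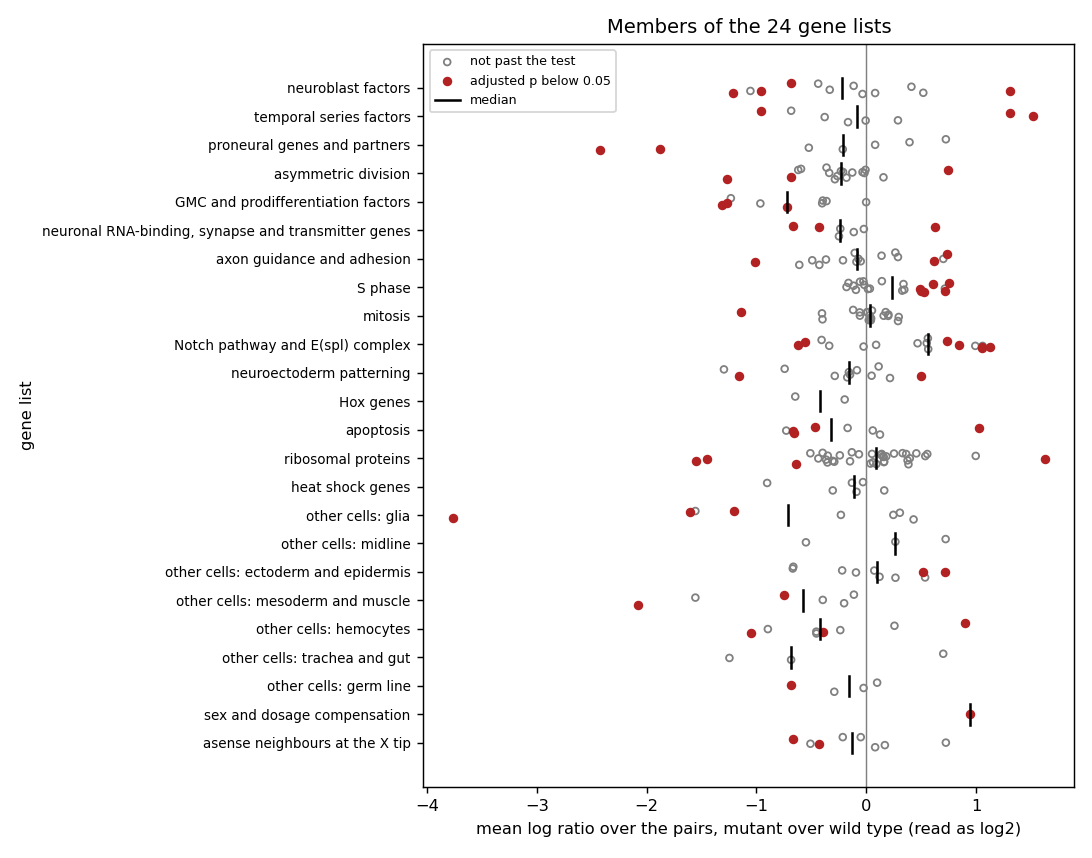
Mean log ratio of mutant over wild type, read as log2, for each measured member of the 24 gene lists, with filled points for genes past the test and a bar at the list median. The prodifferentiation list (median -0.72), the S phase list (0.23) and the Notch list (0.56) passed camera at the preset correlation and did not with an estimated one. Camera does not test the median drawn.

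Dye orientation had no call. Limma gave 0 of 8295 features a dye term past the threshold, with 334 at an unadjusted p below 0.05 against 414.8 expected. Arrays of the same pair correlated across probes at 0.282 to 0.413 (median 0.289, 3 couples) and arrays of different pairs at 0.278 to 0.615 (median 0.386, 25 couples). Genes are not independent replicates, and these correlations describe the arrays only.

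**Figure D3:**
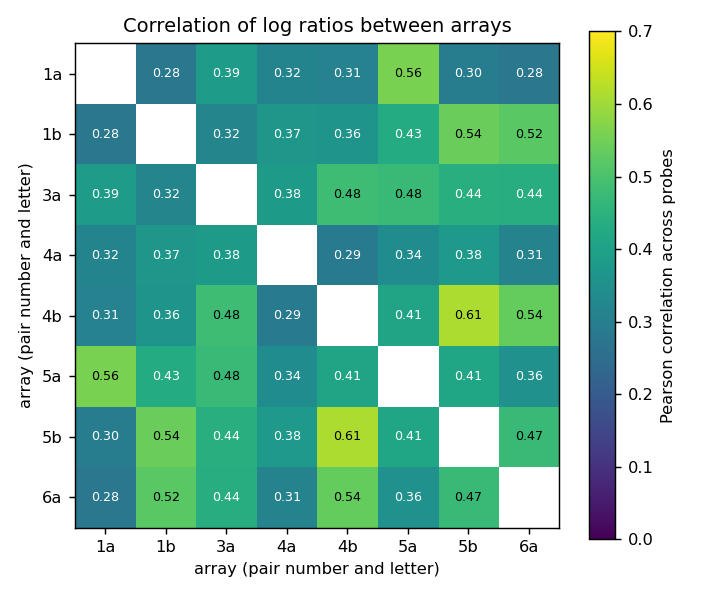
Pearson correlation of log ratios across measured probes between the 8 arrays, named by pair number and letter. The couples 1a with 1b and 4a with 4b lie at 0.282 and 0.289, and the highest value, 0.615, is between arrays 4b and 5b.

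Of the 76 named genes past the limma test, 17 kept the call in each other setting that tested them, 59 lost it in at least 1 and 0 changed direction. These counts leave out the Cy5 over Cy3 reading, which called 0 features. Among list members sens, tap, aurB and E(spl)m2-BFM kept it, while elav, Appl, Cdc6, Mcm2, neur, Diap2 and Hml lost it whichever pair was left out. The call was lost without pair 1 for 20 of the 76 genes, without pair 3 for 16, without pair 4 for 29, without pair 5 for 31 and without pair 6 for 19.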

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

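Tests of the neuroblast share, of centring and of both accounts of the repeat arrays were chosen only after the results were seen.

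In 4 cases a single pair lay far from the other 4. The log ratio of TM4SF was -1.41 in pair 3, next to -3.09 in the nearest pair. CG15098 was at 5.99 in pair 6 against 3.85, CG16813 at 4.37 in pair 6 against 2.40, and svp at -1.49 in pair 6 against -0.93. Chance flags about 1 in 20, which is 4.65 of the 93 groups of values examined.

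In mutant cells 3 of 9 prodifferentiation genes fell and 6 of 20 S phase genes rose, with an adjusted p = 0.865 for each list with an estimated correlation, 0.0940 for the prodifferentiation list without pair 6 and 0.0856 for the S phase list without pair 5. All 16 sign patterns of the 5 pairs were fitted. The real pattern called 1517 features, the highest other called 0, and 1 of the 16 reached the real count. But 16 patterns are too few for a share under 0.05. The count is over all features and was not made for the prodifferentiation and S phase lists. The pairs correlated with each other at 0.42 to 0.65, so turning any of them cancels what they share and lowers the count. The medians of measured values on the arrays lay between -0.18 and -0.02, while the prodifferentiation list median averaged -0.71 over pairs. Offsets of that size are too small to be the whole account of this list. After centring its median stayed below 0 by 4.16 standard errors, an outcome largely set by these sizes, so it adds no separate support. For the S phase list centring moves values the other way and tests nothing. A larger share of neuroblasts in the mutant samples would raise the neuroblast list, whose median averaged -0.31 over pairs (95% interval -0.59 to -0.03). After centring the interval was -0.55 to 0.08, and members of the neuroblast list went both ways. Among lists of other cells, the medians of glia, mesoderm, hemocytes, trachea and gut, and germ line lay below 0. Those of ectoderm (0.10) and midline (0.26) lay above 0, and over all 5 pairs camera called none of these lists that it tested. A changed mix of cells may contribute and cannot be told apart from an effect of asense within cells.

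Repeat arrays of a pair resembled each other no more than arrays of different pairs. If they shared the errors of 1 amplified RNA, their mean correlation of 0.328 would be high, but 404 of the 420 ways to link 3 couples of arrays gave a value as high. That count measures the same low correlation again, so it restates the observation and adds no separate support. A batch marked by the letter stays open, since the 3 arrays b had a mean correlation of 0.506 and 4 of 56 choices of 3 arrays reached it. No biological explanation was tested. Array a alone gave 474 calls and array b of pairs 1, 4 and 5 gave 359.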

How the results depend on the processing

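Array b alone, kept zeros and 8 separate replicates were chosen after the data were seen. The 1517 calls (578 higher, 939 lower, 3 lists) became 0, 0, 0 and 0 lists with values read as Cy5 over Cy3, where asense was at 1.34 and limma gave 117 features an unadjusted p below 0.05. Array a of each pair gave 474 calls (189 higher, 285 lower) and 1 list, array b of pairs 1, 4 and 5 gave 359 (133 higher, 226 lower), and kept zeros gave 345 (141 higher, 204 lower) over 13819 features; for these the cause was not tested. An adjusted p below 0.1 gave 2490 (967 higher, 1523 lower), by construction. No list passed with genes measured on all 8 arrays (0), with 8 separate replicates (0) or with an estimated correlation (0), and fry called 5; the cause was not tested. Leaving out each pair gave 597 to 1309 calls, 240 to 455 higher and 357 to 854 lower, with fewer samples in each fit. Reversed values of genes not past the test were Hsp70Ab, Hsp70Ba and Hsp27, which ran from -0.514 to 0.264, from -0.674 to 0.212 and from -0.0246 to 0.316 when each pair was left out, and, for array b, Scr at 0.0311 and btl at -0.194. Up to 20 other settings were run on a single gene. Asense kept its sign and its call in all settings but the Cy5 over Cy3 reading. Each ratio already sets a mutant sample against its paired wild-type sample. All 8 arrays with the pair as a random block (correlation -0.202) gave 2243 calls (841 higher, 1402 lower), and among named genes lost Mcm2 (0.42) and slou (-0.71). A negative correlation makes repeat arrays count for more than separate replicates, so the 2243 may be too high. Counting 8 arrays as 8 replicates gave 1732 calls. A dye term gave 1108 calls (426 higher, 682 lower). Over all settings 5 named genes without a call gained one, in an unchanged direction: Hsp26 and Tl in 6 settings each, peb in 4, vvl in 2 and btl in 1, some of these with the looser threshold. The planned gene list test with that block was not run. Signal over background was not analysed here.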

Other observations

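The test of the X chromosome was chosen after the result was seen.

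Called genes were spread unevenly over the chromosome arms. On 2R 22.1% of tested genes were called against 17.6% elsewhere (odds ratio 1.33, Fisher's exact test, adjusted p = 7.74e-04 over 6 arms), and 6 of the 12 largest increases, MFS16, CG15098, jtb, Dnaaf3, Aldh-III and hbs, lie there, but 1 of the 12 largest decreases does. Calls of size 1.5 or more made up 2.06% of tested genes on 2R and 2.45% on 3L. Neighbouring genes are not independent, so this p is too small. Differences carried on the X between the balancer and the asense chromosome would raise the share of calls on the X, which was 16.4% against 19.0% elsewhere. The odds ratio was 0.841 (95% interval 0.705 to 1), which argues against a large excess on the X. Neighbouring genes are not independent, so this interval is too narrow and a small excess stays open. Background differences on the autosomes and a difference in the sex of the embryos between the groups were not tested.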
